A study of Homo sapiens with 4 samples.

How the data were processed

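The data were 2 input and 2 RBM24 IP libraries of CAL27 cells. Per the labels' protocols, cells were irradiated with ultraviolet light, lysed in a buffer with SDS, NP-40 and deoxycholate, and treated with DNase and micrococcal nuclease, and libraries were made with a KAPA RNA kit and sequenced as 150 nt paired ends on an Illumina NovaSeq. The labels state the crosslinking dose for all 4 libraries. The series' design text speaks of cells over-expressing RBM24 and of binding sites of RBM25 where the labels name RBM24, and the groups were taken from the labels.

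The authors deposited read counts per gene as whole numbers, with Ensembl gene IDs, symbols and gene types, for 23385 genes, each with at least 1 read in some library. Reads were aligned with HISAT2 to GRCh38, per the submitters' processing notes. The aligner's version, the counting tool, the annotation's version, the strand setting and the treatment of duplicates and of reads with several matches are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. The authors also deposited FPKM values of the same genes. The ratio of FPKM to count was 1 constant per library times 1 constant per gene, and the library totals implied by it were not the sums of the gene reads, so FPKM carries another scaling than the counts. Binding sites and peaks were not analysed here, and counts per gene do not show where in a transcript reads fell.

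Counts were analysed as deposited. Genes were kept by edgeR's filterByExpr with the group and its minimum count of 10 (3221 kept, 20164 left out, the kept genes holding 80.1% of reads). Library sizes were the reads in kept genes with TMM factors between 0.875 and 1.14, and TMM CPM are on that scale, while RPM relates to all gene reads of a library. A quasi-likelihood model with 1 term for IP was fitted in edgeR 4.0.16 under R 4.3.3 (2 residual degrees of freedom per gene, common dispersion 0.0169, prior degrees of freedom 11.2), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The fitted log2 fold is IP minus input. Its standard error was computed from the fitted F statistic. Where a group had no read the fold is a bound against a floor of 3 reads over the group, and where it had 1 to 3 reads the ratio of reads is given with its exact 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules. A floor of 3 reads is 11.3 and 9.39 RPM in the inputs and 40.6 and 36.4 in the IPs.

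Genes named in the text followed a rule written before the data were examined. Of the genes past the threshold with both IP libraries on the same side of both inputs and a mean CPM of 5 or more, it takes the 10 protein-coding and 5 other genes with the largest fitted fold per direction. It adds genes fixed beforehand, among them RBM24, TP63 and CDKN1A, and the 3 members with the smallest p of each list. Members named beyond it, to spell out short counts, were chosen after their values were seen. These are HNRNPU, RPL4, RPS27A, PLAU, TUBA1B, B2M, IFI27, ISG15, JUN, DNAJB1, TXNIP, DSC3, MIR31HG, TUG1, SNHG12, MT-RNR1, MT-ND5, RN7SL1, RPPH1, SCARNA2, SNORD17, TERC, RNU4-1, RNU11, SCARNA10, SNORD13, RNU5A-1, RNU1-1 and RNVU1-29. Also chosen then were the family sums of U3, 5S, 7SL, U5, U1 and U4 RNAs, also as sums of FPKM, and the gene classes. Some genes and 1 list that the rule or the lists take are not reported here. Coordinates are those of RefSeq on GRCh38.p14, matched by symbol and chromosome (18508 of 23385 genes), and are given for a few genes.

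In all 22 gene lists were fixed before the data were examined. The 17 with 5 or more tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 17. Gene classes were compared with the other tested genes by Fisher's exact test with Benjamini-Hochberg adjustment. The inputs and the IPs were compared within their group by chi-square tests of their counts over genes with at least 10 reads in the pair. Across 2076 genes, log2 CPM correlated at a Pearson r of 0.958 between inputs, 0.772 between IPs and 0.635 to 0.652 between input and IP; genes are not independent replicates. Genes seen at equal depth were counted after thinning each library to 73893 reads.

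The fit was tested on simulated counts with 200 changed genes in each of 5 draws. For IP against input, over 3223 genes on average, it recovered 34.4% of 2-fold, 98.2% of 4-fold and 100% of 8-fold increases, and 23.5%, 53.6% and 71.5% of decreases of these sizes, with 4.14% false calls. Of 10 unchanged lists 0 were called, and of 5 shifted lists all 5.

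Alternatives fixed before the data were examined were other scalings, DESeq2 1.42.0, no and other low count filters, the replicate number as a block, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1 and with a minimum mean FPKM of 0.5 or none, leaving out mitochondrial genes and small structured RNAs, glmTreat against a fold of 1.5, and leaving out each library. Summing the inputs as 1 sample, protein-coding genes alone, and a filter of 10 reads in 2 libraries were added after seeing the data. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 did the remaining computations.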

Results

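CAL27 is an established human cell line from a squamous carcinoma of the tongue, and RBM24 is an RNA-binding protein with 1 RNA recognition motif that is known to act in splicing and mRNA stability. The series title places the libraries in a study of RBM24 and apoptosis in these cells, and the question put to them was which RNAs RBM24 binds. Cells were crosslinked with ultraviolet light at 400 mJ/cm2 and lysed, the lysate was treated with DNase and then with micrococcal nuclease, and RNA recovered with RBM24 by immunoprecipitation (IP) was sequenced beside RNA of the lysate (input). This is the iRIP-seq assay. There were 2 input and 2 IP libraries. The labels do not say whether equal replicate numbers share a lysate or whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No IP with a control antibody was analysed here, so the comparison sets IP against input only.

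The libraries were shallow. Input replicates 1 and 2 held 265474 and 319352 reads in genes, and IP replicates 1 and 2 held 73893 and 82413. At 73893 reads per library, a read was seen in 10247 and 10272 genes of the inputs, in 14774 genes of IP replicate 1 and in 10346 genes of IP replicate 2. The 20 most abundant genes took 23.1% ± 0.714 (SD, n = 2) of the input reads and 34.3% ± 1.95 (SD, n = 2) of the IP reads. The inputs differed by no more than sampling noise once the multi-copy small nuclear, 5S, 7SL and U3 RNA genes were set aside (chi-square per degree of freedom 0.972 over 7325 genes). With these genes the value was 1.04 over 7409 genes, and the copies of U1 RNA showed the difference most plainly, with 140 and 6 reads in RNU1-1 and 3 and 135 in RNVU1-29. The IP pair differed by more than sampling noise (3.29 over 2458 genes). Outside the multi-copy genes the inputs thus showed counting noise only (chi-square p = 0.957; p = 0.015 over all genes). They were kept as 2 samples because the labels name them so, which the chi-square tests do not support outside these genes. If they are 1 sample the p-values are too small. Even as 2 samples they share 1 dispersion per gene with the IPs, which differed by more. The p-values may thus be too small for genes that vary between the IPs. The count of calls with the inputs summed, where the spread came from the IPs alone, stands beside the main one.

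Protein-coding genes held a smaller share of the reads in the IPs than in the inputs, and several classes of small and ribosomal RNAs a larger one. A few families carried the larger shares in part. They carried them in full for small nucleolar RNAs and, in IP replicate 2, for nuclear-encoded ribosomal RNA. Protein-coding genes held 71.6% ± 0.666 of the gene reads in the inputs and 57.6% ± 0.473 in the IPs (SD, n = 2). The class of miscellaneous RNAs, which holds the 7SL RNA of the signal recognition particle and its copies, held 4.15% ± 0.165 in the inputs and 9.74% ± 2.19 in the IPs. Small nucleolar RNAs (snoRNAs), which guide modification and processing of ribosomal RNA, held 1.96% ± 0.00341 and 3.97% ± 1.06. Without the 4 copies of U3 they held 1.55% and 1.54% in the inputs and 0.834% and 1.34%, a smaller share, in the IPs. Genes typed as microRNA held 0.0748% ± 0.0067 and 0.929% ± 0.605. MIR3648-1 and MIR3648-2 held 262 of the 370 reads of this class in IP replicate 1 and 879 of 1118 in IP replicate 2. Without these copies the shares were 0.0584% and 0.0748% in the inputs and 0.146% and 0.29% in the IPs. Nuclear-encoded ribosomal RNA genes held 0.16% ± 0.0118 and 0.572% ± 0.207. Without the 5S copies they held 0.0972% and 0.101% in the inputs, 0.332% in IP replicate 1 and 0.0801% in IP replicate 2. Without 7SL the miscellaneous class held 0.437% and 0.429% in the inputs and 0.75% and 0.76% in the IPs. With all genes of each of these 5 classes both IP libraries lay on the same side of both inputs, but with 2 libraries against 2 an exact two-sided permutation test cannot give a p below 0.333. Mitochondrial ribosomal RNA took 11.5% of IP replicate 1 (95% exact interval 11.3 to 11.7) and 6.47% of IP replicate 2 (6.31 to 6.64), against 5.65% and 5.27% of the inputs. Processed pseudogenes took 0.671% of IP replicate 1 (0.614 to 0.733) and 0.181% of IP replicate 2 (0.153 to 0.212), against 0.211% and 0.204% of the inputs. Intervals cover counting error only.

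**Figure D1:**
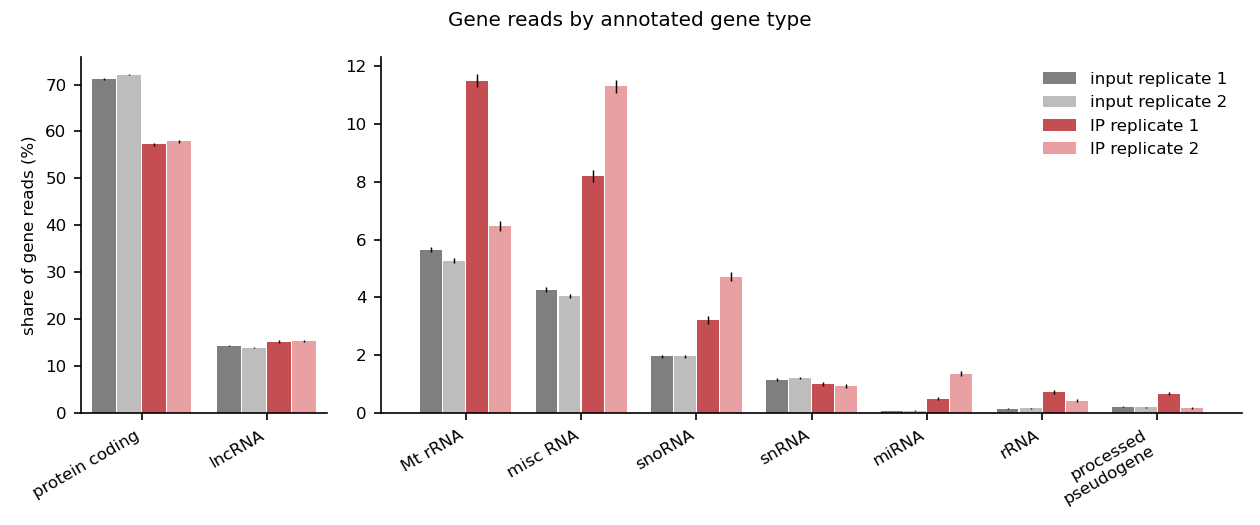
Share of gene reads, in percent, by annotated gene type in each of the 4 libraries; bars are single libraries and error bars are 95% exact binomial intervals. Protein-coding genes took 71.6% of reads in the inputs and 57.6% in the IPs on average, the miscellaneous RNA class 4.15% and 9.74%, and mitochondrial ribosomal RNA (Mt rRNA) differed between the IP libraries at 11.5% and 6.47%.

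Among 3221 genes with enough reads to test, 184 were higher and 178 lower in IP than in input (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 182 and 173 of these differed at least 2-fold. Among the 10 leading protein-coding increases, aldehyde dehydrogenase ALDH1A1 (chromosome 9, 72900671 to 72953053, GRCh38) had 0 and 1 reads in the inputs and 55 and 15 in the IPs, a ratio of 348 with a counting interval of 60.4 to 13934. The aldo-keto reductase AKR1B1 and carbonic anhydrase CA12 likewise had 1 input read in all, with ratios of 244 (interval 41.7 to 9812) and 164 (27.5 to 6671). The inputs had no read for AKR1B10, KRT81 and AKR1C1, which were at least 54.7-fold, 44.7-fold and 39.8-fold higher in IP against a floor of 3 reads over the 2 inputs. Tissue transglutaminase TGM2 rose from 25.1 ± 11.4 to 914.2 ± 943.3 TMM-scaled CPM (SD, n = 2), a log2 fold of 5.09 (SE 0.72, adjusted p = 6.4e-04, edgeR). The mucin MUC5B (log2 fold 4.54), the interferon-induced IFIT1 (4.44) and the insulin-like growth factor binding protein IGFBP4 (4.19) completed the leading 10. AKR1B1, AKR1B10 and AKR1C1 belong to families of close paralogs, and KRT81 to a family of similar hair keratins, so reads between members are uncertain.

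Libraries weighed unequally in these counts. All 18 protein-coding genes at least 8-fold higher in IP had more reads in IP replicate 1 than in IP replicate 2, with 530 reads against 154, or 3.84 times as many in RPM, which relates to all gene reads (95% exact interval 3.2 to 4.62). Without IP replicate 1 the log2 fold of ALDH1A1 was 6.57, that of TGM2 3.25 and that of IGFBP4 3.04, all past the threshold, while AKR1B1, AKR1B10, AKR1C1, CA12, KRT81, MUC5B and IFIT1 had too few reads to be tested. Without input replicate 1, 56 genes were higher and 34 lower, without input replicate 2, 62 and 40, and with the inputs summed as 1 sample, 57 and 37 of the 1846 genes tested. Without IP replicate 1 the counts were 201 and 306, and without IP replicate 2 they were 190 and 305. Without an IP library the spread came from the inputs alone, which showed counting noise only outside the multi-copy genes. Passing in such a fit leaves out the spread between the IPs and is no support for a gene or list. DESeq2 called 70 higher and 51 lower. Scaling by library size alone gave 114 higher and 372 lower, and the deposited FPKM values gave 43 and 912. The scaling of the FPKM values moved most genes down (median log2 fold of all genes -0.74; -1.42 with a pseudocount of 0.1 and -0.23 without filter), so a value under 0 there need not lie below that of the typical gene.

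**Figure D2:**
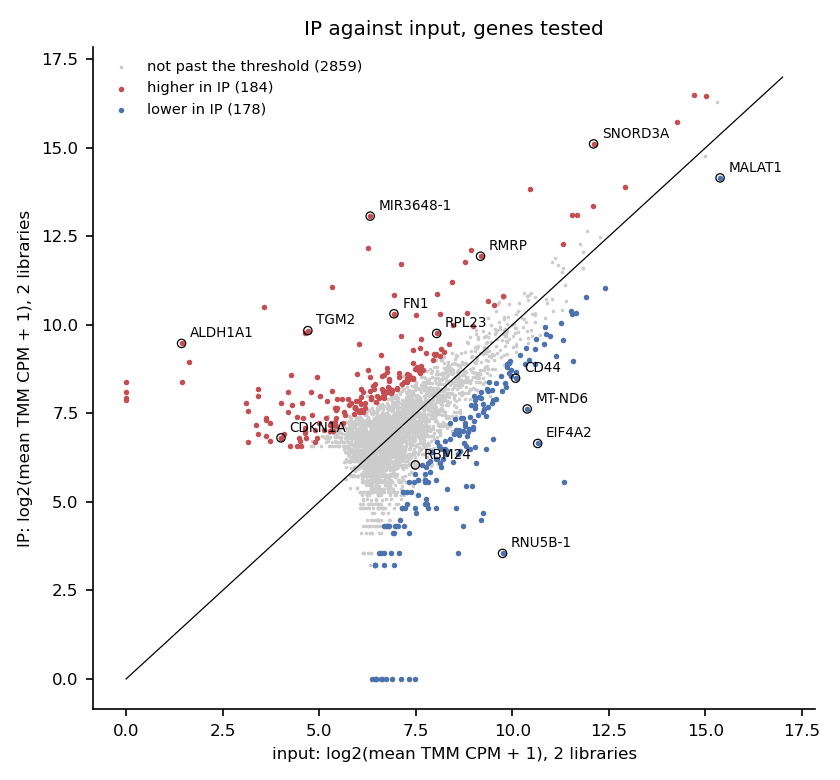
Mean level of each of the 3221 tested genes in the 2 input libraries (horizontal axis) and the 2 IP libraries (vertical axis), both as log2 of TMM-scaled CPM plus 1, with the line of equality. Red points are the 184 genes higher in IP, blue points the 178 lower in IP and grey points the 2859 not past the threshold; circles mark genes named in the text.

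Of the 184 higher genes, 134 were protein-coding and 17 long noncoding RNAs, and structured noncoding RNAs were among the others. SNORD3A, a copy of the U3 snoRNA that acts in processing of the ribosomal RNA precursor (chromosome 17, 19188016 to 19188232), rose from 4399 ± 58.3 to 35367 ± 4962 TMM CPM (SD, n = 2; log2 fold 3.01, SE 0.28, edgeR adjusted p = 2.0e-05). The copy SNORD3B-2 rose by a log2 fold of 5.74, MIR3648-1 by 6.80 and MIR3648-2 by 6.93, and a long noncoding RNA gene of chromosome 17 known by a clone name by 5.91. The 5S pseudogene RNA5SP74 had no input read and was at least 39.8-fold higher. Of the 11 tested genes typed as ribosomal RNA, 8 were higher and none lower. Of the 8 tested miscellaneous RNAs, 6 were higher and none lower. Fisher's exact test against the other tested genes gave adjusted p = 5.6e-08 and 2.7e-06 for the higher genes of these classes. The test counts near-identical copies of 1 RNA, such as 5S or 7SL, as separate genes. These p-values are thus too small as evidence on separate RNAs. Since such genes have near-identical copies, reads may be split between them, and values were also taken over families in RPM. The U3 family was 5.67-fold higher in IP replicate 1 and 8.05-fold in IP replicate 2 than in the pooled inputs, the 5S family 6.29-fold and 5.62-fold, and the 7SL family 2.01-fold and 2.84-fold. The folds were smaller in the FPKM data, at 2.32 and 4.28 for U3 and 2.61 and 3.02 for 5S. There the 7SL sum in IP replicate 1 was lower than in the inputs (0.82, against 1.51 in IP replicate 2). The fixed list of small structured RNAs had 9 members higher, 4 lower and 8 not past the threshold (10 higher and 6 lower adjusted over the list alone). RMRP, the RNA of ribonuclease MRP, rose by a log2 fold of 2.76 and RPPH1, the RNA of ribonuclease P, by 1.56. RN7SL1 rose by 1.78, SCARNA2, a guide RNA of Cajal bodies, by 2.19, and TERC, RNU4-1, RNU11 and SNORD17 by 1.19, 0.95, 1.85 and 1.44, SNORD17 lying at -0.094 in the FPKM data. The list's median log2 fold was 0.40 and its mean -0.06. The median was under 0 without the low count filter, in the FPKM data and without IP replicate 1. Its test pointed higher and did not pass the threshold (camera adjusted p = 0.11; adjusted p = 0.68 with an estimated correlation). It passed as higher in DESeq2 (adjusted p = 0.0018), with CPM of 1 or more in all 4 libraries (0.047) and with 10 reads in 2 libraries (0.013). It also passed as higher without either IP library, on the spread of the inputs alone. It pointed lower without input replicate 2, without the low count filter and in the filtered FPKM data, and passed as lower in the FPKM data without filter (adjusted p = 0.0036).

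Other small RNAs went the opposite way. The U5 RNA of the spliceosome had 389 and 443 reads in the inputs, 4 in IP replicate 1 and 0 in IP replicate 2, at least 39.1-fold lower in the latter against a floor of 3 reads. RNU5B-1 had 455 input reads and 1 IP read, a ratio of 91.6 (counting interval 16.3 to 3624), and RNU5A-1 had 312 and 2, a ratio of 31.4 (8.62 to 260.3). The U1 family was at 0.978 and 0.966 of its input level and the U4 family at 1.2 and 1.16, but at 0.405 and 0.52 and at 0.495 and 0.622 in the FPKM data. Of 22 tested H/ACA snoRNAs, which guide pseudouridylation, 13 were lower and none higher (Fisher's exact adjusted p = 4.7e-11 for the lower genes), whereas 6 of 13 tested C/D snoRNAs were higher and 5 lower. The 6 included SNORD3A and SNORD3B-2, near-identical copies of U3 counted as separate genes. Without the U3 copies the share of snoRNA reads was lower in both IPs than in both inputs. SCARNA10 (log2 fold -1.92) and SNORD13 (-1.67) were the other fixed-list members that fell. Of the 5 leading noncoding decreases, the snoRNAs SNORA33, SNORD105B and SNORA2A, the mitochondrial histidine tRNA MT-TH and the intronic transcript N4BP2L2-IT2 had no IP read and were at least 4.9-fold, 4.23-fold, 3.55-fold, 3.76-fold and 5.63-fold lower.

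Protein-coding transcripts lower in IP included those of the splicing factor ZRANB2 and the ubiquitin ligase LTN1, which had no IP read and were at least 3.15-fold and 2.95-fold lower. EIF4A2, an RNA helicase of translation initiation (chromosome 3, 186783577 to 186789897), fell from 1613 ± 17.5 to 99.5 ± 70.8 TMM CPM (SD, n = 2; log2 fold -4.09, SE 0.41, edgeR adjusted p = 3.4e-05). Its introns are known to host snoRNAs, and whether reads fell on exons or introns is not given by counts per gene. TOP1, FZD6, SPATA5, IARS2, NBPF14 and RP1-65P5.6 had 1 IP read each against 50 to 72 input reads, with ratios of 14.5 (interval 2.52 to 580.1) for TOP1 down to 10.1 (1.72 to 405.2) for RP1-65P5.6. Without IP replicate 1, IARS2 no longer passed the threshold (adjusted p = 0.082).

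**Figure D3:**
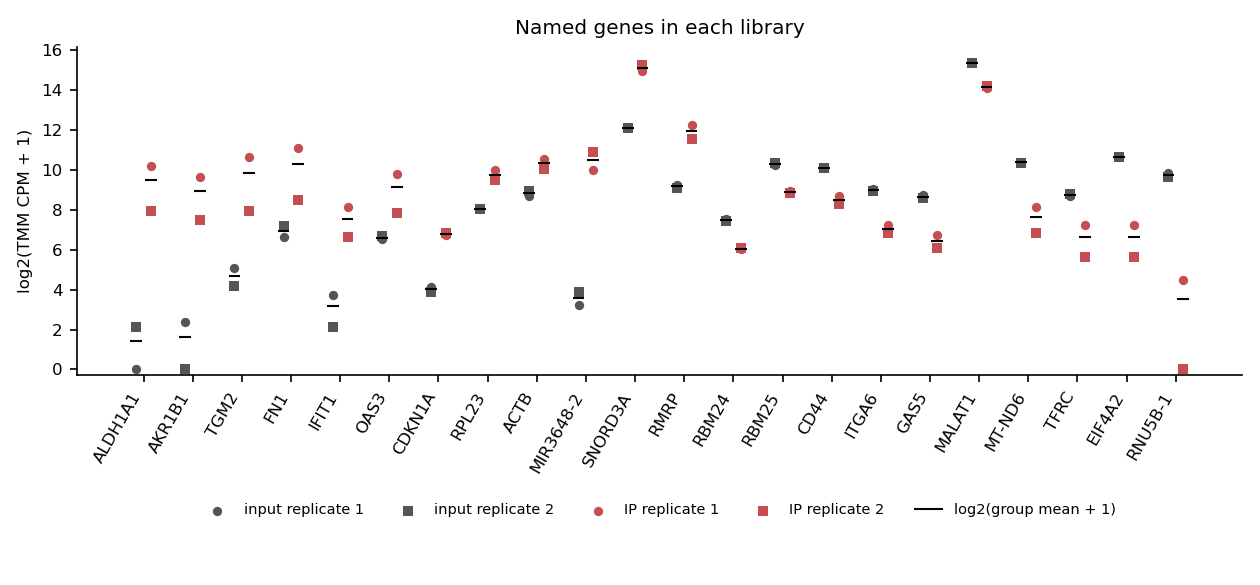
Level of 22 named genes in each library as log2 of TMM-scaled CPM plus 1; grey symbols are inputs and red symbols IPs, circles replicate 1 and squares replicate 2, and short lines the log2 of the group mean plus 1. ALDH1A1, TGM2 and FN1 lie higher in IP replicate 1 than in IP replicate 2, while SNORD3A, RPL23 and CDKN1A lie above both inputs at like levels in both IPs.

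The transcript of RBM24 itself had 45 and 50 reads in the inputs and 3 and 4 in the IPs, which corresponds to 179 ± 11.3 and 65.01 ± 1.28 TMM CPM (SD, n = 2). The log2 fold of -1.44 (SE 0.47) did not pass the threshold (edgeR adjusted p = 0.066). It passed when scaled by library size alone (-1.79, adjusted p = 0.021), by the upper quartile (-1.56, adjusted p = 0.046), without the low count filter (-2.0, adjusted p = 0.012), with CPM of 1 or more in all 4 libraries (-1.81, adjusted p = 0.022), and in the FPKM values with filter (-2.30 and -2.88). The cell cycle inhibitor CDKN1A, among transcripts reported as RBM24 targets, rose from 15.1 ± 2.07 to 111.1 ± 6.03 TMM CPM (log2 fold 2.83, SE 0.57, adjusted p = 0.0067), on 8 input and 12 IP reads. Without IP replicate 1 it no longer passed (2.83, adjusted p = 0.12), and without IP replicate 2 or either input it had too few reads to be tested. TP63, with 7 and 16 against 2 and 2 reads, was not tested. CDKN1A was the 1 of 5 tested members of the reported targets that passed (2 adjusted over the list alone), and FXR1 was at a log2 fold of -0.80 (adjusted p = 0.36). The list did not pass (median 0.23, camera adjusted p = 0.30), though fry, which does not compare it with other genes, gave an adjusted p of 0.034, and its median was under 0 with library size alone, with CPM of 1 or more in all 4 libraries and in the filtered FPKM data.

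None of the 16 tested apoptosis genes passed the threshold over all genes or over the list alone in the edgeR test. The list's median log2 fold was 0.17 (camera adjusted p = 0.61), and it was under 0 with library size alone, in the FPKM data, without either input and with the inputs summed. DIABLO and XIAP, an activator and an inhibitor of caspase activation, lay at 1.30 (adjusted p = 0.081) and 1.15 (0.09) and BBC3, which promotes apoptosis, at 1.24 (0.14), all 3 under 0 in the FPKM data (pseudocount 1) but above the median of all genes there, -0.74. Without IP replicate 1 DIABLO lay at 1.55. Of 10 tested cell cycle genes, CENPF, which acts at the kinetochore, was lower (log2 fold -2.17) and none was higher (0 and 1 adjusted over the list alone), with MCM4 at 1.56 (adjusted p = 0.075) and MKI67 at 1.01 (0.15). The cell cycle list's median, -0.15, was above 0 with CPM of 1 or more in all 4 libraries, without either input and with the inputs summed (camera adjusted p = 0.98). The list passed as lower in the FPKM data without filter (adjusted p = 0.0115). Of 27 genes of head and neck cancer signalling, the receptor MET fell by a log2 fold of 1.28 and the others did not pass (camera adjusted p = 0.98; median 0.17, under 0 with library size alone, without the low count filter, with CPM of 1 or more in all 4 libraries and in the FPKM data). Among these were FAT1 at -0.92 (adjusted p = 0.053) and EGFR at -0.70 (adjusted p = 0.12). EGFR lay at -0.51 without IP replicate 1 and at -1.25 without IP replicate 2. The list passed as lower without the low count filter (adjusted p = 0.014) and in the FPKM data without filter (0.0011).

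Interferon response genes had the largest median shift of the tested lists in the edgeR test, at a log2 fold of 1.59. The median was 0.63 with 10 reads in 2 libraries, where housekeeping genes (0.80) and small structured RNAs (0.75) had larger ones. Of 12 tested members 6 were higher and none lower (7 higher adjusted over the list alone), among them IFIT1, IFI6 (log2 fold 1.87), the oligoadenylate synthetase OAS3 (2.44), IFI27 (3.35) and ISG15 (3.20). The list passed with the preset correlation (camera adjusted p = 4.6e-04) and not with an estimated correlation (adjusted p = 0.68). It held 1620 and 1525 RPM in the inputs, 4236 in IP replicate 1 and 1747 in IP replicate 2. Without IP replicate 1 the median was 0.11 and the list did not pass (adjusted p = 0.45), and OAS3, IFI27 and ISG15 each lost their call (adjusted p = 0.093, 0.35 and 0.065). In the FPKM data the list's median was -0.053, where that of all genes was -0.74, and without filter there the list did not pass (adjusted p = 0.11).

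Housekeeping genes split. ACTB and GAPDH rose by log2 folds of 1.47 and 1.51 and TUBA1B by 1.76, whereas the transferrin receptor TFRC and B2M fell by 2.19 and 1.64, and 10 of 16 did not pass. The list passed (median 0.75, camera adjusted p = 0.031, but 0.68 with an estimated correlation). Its median was under 0 without the low count filter and in the FPKM data, where ACTB too lay under 0 and the median of all genes was -0.74. By its median the list lay below the typical gene there with a pseudocount of 1, filtered or not, and above it with 0.1. It did not pass without IP replicate 1 (adjusted p = 0.63), where TUBA1B lost its call, nor without input replicate 1 (0.16) or 2 (0.13), with the inputs summed (0.12), with library size alone (0.058) or with CPM of 1 or more in all 4 libraries (0.13). In the FPKM data without filter it passed as lower (adjusted p = 0.0103). It took 5243 and 5402 RPM in the inputs, 7186 in IP replicate 1 and 4951, below both inputs, in IP replicate 2. Of 69 cytosolic ribosomal protein genes, 10 were higher (15 over the list alone), led by RPL23 (log2 fold 1.70), RPL12 (1.87) and RPL38 (1.59), and RPL4 and RPS27A were lower (-1.45 and -1.66). The list did not pass (camera adjusted p = 0.23), its median of 0.18 being under 0 with library size alone, without the low count filter, with CPM of 1 or more in all 4 libraries, in the FPKM data and without IP replicate 1. It passed as higher with 10 reads in 2 libraries (adjusted p = 0.029), and as lower without the low count filter (2.2e-04) and in the FPKM data (0.026 and 0.0204; without filter 7.4e-10). RPL38 lost its call without IP replicate 2 (adjusted p = 0.086). Ribosomal protein genes have many pseudogene copies, so their counts are uncertain. Among 18 stress and immediate early genes, the AP-1 members FOSL2 (1.59), JUND (1.94) and JUN (1.53), the phosphatase DUSP1 (2.29) and the chaperone DNAJB1 (1.70) were higher (7 adjusted over the list alone), and TXNIP, with 84 input and 2 IP reads, was lower (ratio 8.45, interval 2.27 to 70.9). The list did not pass (median 0.45, under 0 without the low count filter, in the FPKM data, without either input and with the inputs summed; camera adjusted p = 0.36). DUSP1 and JUN lost their calls without IP replicate 1, and JUND and DNAJB1 without IP replicate 2.

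The list of mitochondrially encoded genes passed with a median under 0 (log2 fold -0.80, camera adjusted p = 0.0019; adjusted p = 0.68 with an estimated correlation). Of 15 tested, 7 were lower (7 over the list alone), led by the respiratory complex I subunits MT-ND6 (-2.82) and MT-ND3 (-2.91), the cytochrome b gene MT-CYB (-1.78) and MT-ND5 (-1.33). The ribosomal RNA MT-RNR1 was the 1 member higher (1.48), at 75405 TMM CPM in IP replicate 1 and 33783 in IP replicate 2, and its fold was under 0 in the FPKM data. The list's summed reads, most of them ribosomal RNA, took 75834 and 70693 RPM in the inputs, 124071 in IP replicate 1 and 70571 in IP replicate 2. The sum thus rose in IP replicate 1, against the median, and lay just below both inputs in IP replicate 2. The list did not pass without IP replicate 2 (adjusted p = 0.066). Of 29 genes for SR proteins and hnRNPs, factors of splicing and RNA packaging, 4 were lower and none higher (6 lower over the list alone), namely SRSF11, HNRNPA2B1 (-1.02), TRA2A (-1.62) and HNRNPU (-0.95). SRSF11 had 95 input and 3 IP reads, a ratio of 6.37 (counting interval 2.12 to 31.4). This list passed as well (median -0.48, camera adjusted p = 0.037; adjusted p = 0.68 with an estimated correlation) and did not without IP replicate 2 (0.14) or without input replicate 1 (0.16) or 2 (0.13) or with the inputs summed (0.12). TRA2A lost its call without either IP library. Among 31 other RNA-binding proteins, RBM25 (1278 ± 60.3 to 476.4 ± 21.2 TMM CPM) and TAF15 were lower, at log2 folds of -1.43 and -1.28 (camera adjusted p = 0.19), and RBM6, with 66 input and 3 IP reads, did not pass (adjusted p = 0.063). This list passed as lower without the low count filter (adjusted p = 9.8e-08) and with CPM of 1 or more in all 4 libraries (0.0025). It also passed as lower in the FPKM data (0.0098 and 0.017, and 2.5e-06 without filter) and, on the spread of the inputs alone, without IP replicate 2.

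Genes of the squamous keratinocyte included the integrin ITGA6 (-1.95) and the desmocollin DSC3 among the lower and the 14-3-3 protein SFN (1.16) among the higher, with 15 of 19 not past the threshold (6 lower and 1 higher over the list alone). DSC3 had 46 input reads and 1 IP read, a ratio of 9.26 (1.58 to 373.4). The list missed the threshold in the edgeR test (median -0.70, camera adjusted p = 0.054; adjusted p = 0.68 with an estimated correlation). It passed as lower with library size alone (adjusted p = 0.037), with the upper quartile (0.042), in DESeq2 (0.0495), with CPM of 1 or more in all 4 libraries (1.6e-04), without the low count filter (1.9e-08), with 10 reads in 2 libraries (0.029) and in the FPKM data (0.0050 and 0.0088; without filter 2.5e-06). It also passed without mitochondrial genes and small structured RNAs (adjusted p = 0.032) and on protein-coding genes alone (0.0145). Without IP replicate 2 it passed on the spread of the inputs alone. It did not pass without IP replicate 1, without either input or with the inputs summed. It took 10170 and 10230 RPM in the inputs, 3898 in IP replicate 1 and 6880 in IP replicate 2. DSC3 lost its call without IP replicate 1 and SFN without IP replicate 2, and SFN lay under 0 in the FPKM data. Of 11 genes of epithelial to mesenchymal transition and matrix, 2 were higher, among them fibronectin FN1 (3.30), and the hyaluronan receptor CD44 (-1.61) and PLAU (-1.08) were lower. The list's median was -0.060 with a mean of 0.28 and a test pointing lower (camera adjusted p = 0.76). The median was above 0 without input replicate 2, without IP replicate 2 and with 10 reads in 2 libraries. FN1 took 2179 TMM CPM in IP replicate 1 and 363 in IP replicate 2, and its log2 fold was 1.49 without IP replicate 1. Among 22 long noncoding RNAs, GAS5 (-2.24), SNHG29 (-1.66) and SNHG12 (-1.17), which host snoRNAs, were lower. So were MALAT1 (-1.23), which is retained in the nucleus, and TUG1 (-1.56). MIR31HG was higher (1.39) but not without IP replicate 2 and under 0 in the FPKM data. The list did not pass (median -0.016, above 0 with DESeq2's size factors, in DESeq2 and with 10 reads in 2 libraries; camera adjusted p = 0.30). It passed as lower without the low count filter (adjusted p = 1.1e-05) and with CPM of 1 or more in all 4 libraries (0.023). It also passed as lower in the FPKM data (0.0084 and 0.015, and 3.6e-05 without filter) and, on the spread of the inputs alone, without IP replicate 2. MALAT1 alone went from 42606 ± 632.6 to 18176 ± 956.7 TMM CPM (SD, n = 2). Of 9 respiratory chain genes of the nucleus NDUFB9 was lower (-1.73), and not without IP replicate 1 (adjusted p = 0.077), while NDUFS8 was at 1.67 (adjusted p = 0.056) and NDUFS1 at 0.59 (0.51). That list's median was 0.12, under 0 with library size alone, without the low count filter, in the FPKM data, without input replicate 1 and on protein-coding genes alone, and its test pointed lower (camera adjusted p = 0.98).

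**Figure D4:**
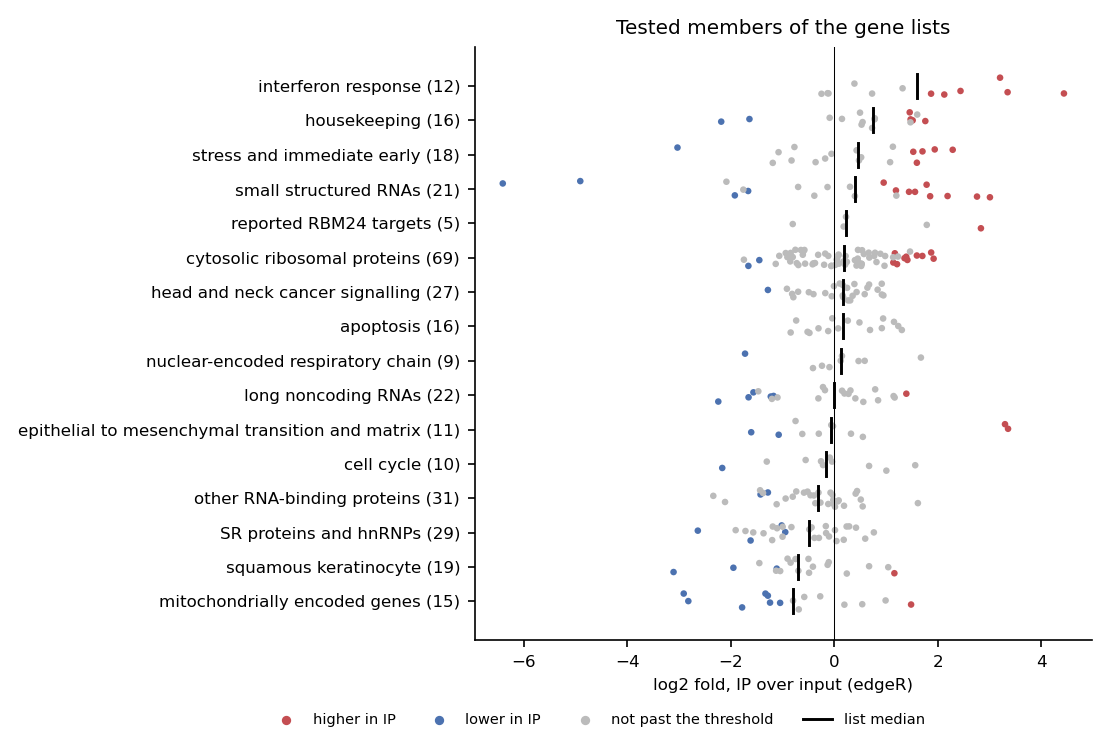
Log2 fold of IP over input from the edgeR test for each tested member of 16 of the 17 gene lists with 5 or more tested members, the number tested in brackets; red points are higher, blue points lower and grey points not past the threshold, and black bars are list medians. Medians run from -0.80 for mitochondrially encoded genes to 1.59 for interferon response genes, the latter 0.11 without IP replicate 1 and -0.053 in the FPKM data, and that of the housekeeping list, 0.75, was under 0 in the FPKM data.

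Of the lists with fewer than 5 tested members, muscle sarcomere genes had 4, fibroblast markers 2 and replication-dependent histones 3, none past the threshold. The sarcomere list took 1107 and 1227 RPM in the inputs, 1353 in IP replicate 1 and 946.5 in IP replicate 2. The histone list took 689.3 and 735.9 RPM in the inputs and 1150 and 970.7 in the IPs. With more members tested it passed as higher without the low count filter (adjusted p = 0.014), with CPM of 1 or more in all 4 libraries (0.039) and in the FPKM data (3.0e-07 and 5.6e-07; without filter 0.036), but not without IP replicate 1 (0.92) or 2 (0.54). No leukocyte or endothelial marker had enough reads to test. Leukocyte markers took 18.8 and 15.7 RPM in the inputs and 40.6 and 0 in the IPs, on 3 IP reads in all. Endothelial markers took 18.8 and 3.13 in the inputs and 108.3 and 24.3 in the IPs, on 6 input and 10 IP reads. The endothelial list passed as higher in the FPKM data without filter (adjusted p = 0.023) and not in the counts without filter (0.066).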

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

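The tests of 1 source, of binding by RBM24, of copies sharing reads and of 5S against U5 RNA were chosen after the results were seen. Signal in data the comparisons do not use was the total behind the FPKM values: per gene read it was 2.49 times that of input replicate 2 in IP replicate 1 and 1.91 times in IP replicate 2, against 1.05 in input replicate 1.

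The 18 protein-coding genes at least 8-fold higher in IP, among them ALDH1A1, AKR1B1, AKR1B10, AKR1C1, TGM2 and FN1, were each read more often in IP replicate 1 than in IP replicate 2. A candidate explanation is RNA or reads from other cells with active NRF2 target genes: a list of 19 such targets written before it was looked at, 18 of them in the data, had 2.62 times the input level in IP replicate 1 (95% exact interval 2.2 to 3.12) and 0.78 in IP replicate 2. AKR1C2 (1 input read, 35 in IP replicate 1), AKR1C3 (1 and 21), ABCC2 (1 and 20) and NQO1 (5 and 14) were higher, while TXNRD1 (208 and 31) lay near the input level and SLC7A11 (199 and 9) below it. Without AKR1C2 and AKR1C3, paralogs of a gene in the pattern, it was 1.79 (1.45 to 2.19), short of the 2-fold set beforehand, and 10 of the 18 had 5 or more input reads, so these are expressed in CAL27 too. Whether 1 source present in different amounts fed all 18 stays open. The reads ratio of 3.44 ran from 1.38 to 4.93 by gene (chi-square heterogeneity p = 0.711). But this test gave a p under 0.05 in only 70.8% of 1000 draws of 18 other higher genes. Binding by RBM24 stays open too, no control IP having been analysed. The median log2 of IP replicate 2 over the inputs was 2.93. It cannot decide, since the genes were picked as higher in a fit that included this library.

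Reads of IP replicate 1 were spread over 14774 genes and those of IP replicate 2 over 10346 at equal depth. RNA from other cells as the whole cause is argued against by reads in 198 genes of olfactory, taste and vomeronasal receptor, keratin-associated protein, beta-defensin and PRAME families, whose level in IP replicate 1 over the inputs had a lower 95% limit of 8.62, as far as these are silent in such cells. Not all can be taken as silent, since epithelia make beta-defensins (3 of these reads in IP replicate 1) and taste receptors, with 24 input reads, were at 0.989, but the 162 olfactory receptor genes alone gave 15.6 (11.3 to 21.6). Reads from DNA or another dispersed background may account for the spread, with a ratio of 11.3 where at least 5 was predicted (138 reads in IP replicate 1, 39 and 58 in the inputs). Against IP replicate 2, the reference first considered, the ratio was 4.96 (3.34 to 7.59), just under that bound; IP replicate 2 itself was at 2.27 times the inputs (1.46 to 3.43), and no biological explanation was tested.

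U3, 5S and 7SL RNA copies were higher in IP and U5 copies lower. Reads shared between copies are argued against by the family sums, of which the smallest fold in either IP library was 2.01, but for 7SL this rests on the scaling, since its sum in IP replicate 1 was 0.82 of the inputs in the FPKM data (U3 2.32, 5S 2.61). Over 87 small noncoding RNA genes, relative gene length and log2 fold had a Spearman rho of 0.333 (permutation p = 0.0017). Genes are not independent. Whether recovery depends on RNA length in this class stays open, since the 87 genes include the copies to be explained. The length was also that implied by the FPKM values, which put U3 at 6.28 times U5. By RefSeq coordinates SNORD3A (19188016 to 19188232) and RNU5B-1 (65304677 to 65304793) lie closer in length. Length does not explain 5S against U5 RNA. Their lengths by the FPKM measure were alike (5S 1.03 times U5), and their IP over input ratios differed at least 165-fold. Binding by RBM24 or its partners cannot be told apart from unspecific recovery without a control IP. The U3, 5S and 7SL sums were at least 2.01 times the inputs per gene read in both IP libraries. These families were picked because their copies were higher, so the sums cannot decide it.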

How the results depend on the processing

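Added after seeing the data were the inputs summed as 1 sample, protein-coding genes alone, and the filter of 10 reads in 2 libraries; all other settings were planned. The main test called 184 genes higher and 178 lower (50.8% higher), 182 and 173 of them at least 2-fold, and 4 of 17 lists. At these read numbers simulated 2-fold changes were recovered in 34.4% (higher) and 23.5% (lower) of cases. The median log2 fold of all genes shifted to -0.34 with library size alone, -0.12 with the upper quartile, -0.14 without filter, and -0.74, -1.42 and -0.23 in the FPKM fits, and changes there are relative to it. Calls higher and lower (of which at least 2-fold) were 114 and 372 (111 and 363; 23.5% higher) with library size alone, 154 and 229 (40.2% higher) with the upper quartile, 70 and 51 (69 and 51) in DESeq2, 160 and 445 (all at least 2-fold; 26.4% higher) without filter, and 150 and 278 (all at least 2-fold; 35% higher) with CPM of 1 or more. FPKM with pseudocount 1 gave 43 and 912, with pseudocount 0.1 39 and 617, and without filter 11 and 205, all at least 2-fold (4.5%, 5.95% and 5.09% higher). The inputs summed gave 57 and 37 (56 and 37), on 1846 genes with spread from the IPs alone, and kept 85 of the 307 main calls tested there. Requiring 1.5-fold by glmTreat left 101 and 86. Leaving out a library gave 56 to 201 higher (56 to 179 at least 2-fold) and 34 to 306 lower (34 to 279). The lone library was assumed to vary like the others. The low ends are without an input, where fewer genes were tested and the spread came from the IPs alone. Fewer genes tested was not the whole reason, since most main calls were still tested there and most of those were not kept. Lists called were 9 without filter, 8 with CPM of 1 or more, 8, 8 and 12 in the FPKM fits, 2 with the inputs summed, 7 with 10 reads in 2 libraries, 0 with estimated correlation, 2 by fry, and 2 to 6 without a library. RBM24 passed with library size alone (-1.79), upper quartile (-1.56), no filter (-2.0), CPM of 1 or more (-1.81) and FPKM (-2.30 and -2.88). Below 0 instead of above were housekeeping genes without filter (-0.043) and in the FPKM fits (-0.75, -0.91 and, without filter, -0.74), and in these 3 fits SFN (-0.34, -0.35 and -0.34), ACTB (-0.035, -0.036 and -0.035), DIABLO (-0.14, -0.24 and -0.14), XIAP (-0.21, -0.33 and -0.21), BBC3 (-0.18, -0.24 and -0.18), MIR31HG (-0.18, -0.23 and -0.18), MT-RNR1 (-0.14, -0.14 and -0.14) and SNORD17 (-0.094, -0.094 and -0.094). Each of these 8 genes lay above the median of all genes in the same fit, except SFN without filter, so the sign followed the common shift. Beyond this shift and fewer genes or samples tested, the cause was not tested. Of 82 named genes past the threshold, 77 kept their call with DESeq2 size factors, 48 in DESeq2 (14 not tested), 47, 41 and, without filter, 21 in the FPKM fits, 30 with the inputs summed (11 not tested), 29 and 31 without input replicates 1 and 2 (11 and 12 not tested), and 63 and 75 without IP replicates 1 and 2 (8 and 1 not tested). With the replicate block, 171 genes were higher and 178 lower. The difference between the IPs and that between the inputs correlated at 0.031 over 2076 genes. Outside the multi-copy genes the inputs differed by counting noise only. The correlation thus cannot show whether equal replicate numbers share a lysate.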

Other observations

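Some abundant transcripts parted the IP libraries in the direction opposite to FN1 and TGM2. AGRN, which codes for the basement membrane proteoglycan agrin, had 152 reads in IP replicate 1 and 410 in IP replicate 2, PLEC, which codes for the cytolinker plectin, 193 and 445, and the amino acid transporter SLC7A5 139 and 337. The nuclear RNA NEAT1 had 1134 and 1906. Of the RNAs read more in IP replicate 1, the 5.8S ribosomal RNA copy RNA5-8SN3 had 147 and 36. These genes were chosen after their values were seen from the 20 that differed most between the IP libraries, and no explanation was tested.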
